A study of Mus musculus with 9 samples.

How the data were processed

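Thymocytes of C57BL/6 mice were sorted by CD4, CD8 and TCRβ and their RNA was measured on 9 one-colour (Cy3) Agilent arrays of design 028005, 1 array per group. Per the labels, control mice carried Tie2-Cre and wild-type Brd1, and conditional knockout (CKO) mice carried Tie2-Cre and Brd1flox/flox. The groups were DP (CD4 and CD8 double positive), CD4SP and CD8SP (single positive) cells of both genotypes at 8 weeks, CD4SP cells without surface TCRβ from the CKO at 8 weeks, and CD8SP cells of both genotypes from OT-I mice at 14 weeks. OT-I is a transgenic T cell receptor restricted by MHC class I. The labels name a protocol with biotinylated cRNA, whereas the scanner files are those of a Cy3 experiment; the arrays are described here by the scanner files.

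The deposited scanner files give, per the file headers, the processed signal of each spot as an intensity, background-subtracted and spatially detrended by Agilent Feature Extraction 10.7.1.1, with no scaling between arrays. They also give the median spot and local background brightness, each an intensity. The deposited series table holds the processed signal divided by the 75th percentile of its array, an intensity on the linear scale; the 75th percentile of every column was 1, and its log2 values correlated with those of the scanner files with r = 1.0 on each array.

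The values here were made from the scanner files. Spots of a probe were averaged, 144 of 55681 probes marked as outliers on an array were left out, and 55537 were kept. The log2 signal of each probe was taken relative to the 75th percentile of all probes on its array, and all levels below are on this scale. RefSeq accessions named 26715 probes with 20258 symbols, and 28822 probes without a symbol were counted and not named. A gene was represented by the probe with the highest mean over the 9 arrays. The names came from a RefSeq table of a later mouse assembly than that of the array design, so no position is given. A gene counted as detected, or well above background, on an array where any of its probes was marked so. As 5389 symbols had several probes, this need not be the probe that gave the value. A difference against a group with no array well above background is given with a bound, computed against the lowest signal well above background on each of its arrays. Where only some arrays of a group were well above background, the fitted value rests partly on signals that were not, and the text gives their number.

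Each array held 59305 spots besides 3671 control spots, and none of the 59305 was saturated. Between 39.01% and 45.9% of probes were well above background, and the median SD between spots of one probe was 0.0713 to 0.0813 on the log2 scale. The number of arrays limits the precision: with 1 array per group, no difference between 2 arrays could be set against a replicate error.

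The genotype effect and the population contrasts were fitted with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), as a linear model with population and genotype as additive terms over all 9 arrays. It left 3 residual degrees of freedom, and the variance prior (constant) added 2.91. The error is therefore the spread of the genotype difference between the 4 populations with both genotypes. The fit tested 20282 genes (12285 named) detected on at least 2 arrays, two-sided, and called those with an adjusted p (Benjamini-Hochberg over all genes) below 0.05. The TCRβ-negative array has no control and does not enter the genotype effect; its contrasts with DP and CD4SP take the genotype effect of the other populations as its own. For each pair of CKO and control arrays, genes detected on at least 1 of them were compared, and those past a 2-fold difference were counted without a p-value. For gene lists, a comparison of 2 arrays gives the percentile of its median among 10000 random lists of the same size, matched on mean signal, as a description only.

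The 25 gene lists were fixed before the data were examined: Brd1 and its partner subunits, co-receptors, T lineage transcription factors and Cd8 regulators, DP stage, DN (double-negative) stage and Notch targets, TCR signal and positive selection, TCR complex and proximal signalling, mature thymocyte and egress, CD4 lineage, CD8 lineage, regulatory T cell, cytotoxic and memory-like CD8, proliferation, p53 targets and apoptosis, interferon-stimulated, immediate early and heat shock, cytokines and their receptors, and markers of B cells, myeloid and dendritic cells, granulocytes, erythroid cells, stroma and epithelium, NK and NKT cells, and gamma delta T cells, with sex-linked genes. In the fit, lists of at least 5 tested members were tested with camera (limma) at its preset correlation of 0.01 and again with an estimated correlation, each adjusted over the lists of a contrast. The genes named were also set by a rule beforehand: Brd1 and the co-receptors on every array; up to 10 largest differences in each direction per comparison, among genes of at least median brightness whose probes all moved the same way (called genes in the fit); and up to 4 members of each list with the largest differences.

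Each array was also placed on an axis from the DP control to the CD4SP or CD8SP control array, as the median over genes that differ more than 4-fold between them of the distance covered. Genotype differences of the 4 pairs were correlated across 15102 genes. On slide 1 lay 6 arrays. The CD8SP CKO array and both OT-I arrays were on slide 2, so the CD8SP pair crosses slides. The genotype effect was also computed with slide as a block and within each slide.

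The alternatives chosen beforehand were normexp background correction (offset 50), quantile normalization, the series table, a stricter and no detection filter, the mean over all probes of a gene, slide as a block, no population term, a variance prior with trend, each pair left out in turn, 1.5-fold and 4-fold thresholds, and a 2-fold axis. The mean spot brightness planned for normexp was not among the columns used here, so it used the median spot brightness. Scaling on the 75th percentile of the probes detected on all 9 arrays was added after seeing the data, because most probes were not detected. The direct difference of the TCRβ-negative array from the DP or CD4SP CKO array, without the fitted genotype effect, was also added after seeing the data.

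The fit was tested on simulated data with 200 changed genes. For genotype it recovered 8% of changes of 1 on the log2 scale, 84% of 2, 98% of 3 and 100% of 4, with 13 false calls. For the TCRβ-negative array against DP it recovered 0%, 6%, 60% and 84% of these sizes, with 5 false calls. Of 100 simulated unchanged lists of 18 genes, 2 fell outside the central 95% of random lists, and all 100 lists moved by 1 lay above. The simulated lists were random genes, and the simulated fit had an additive model with noise independent between genes. These figures therefore do not cover correlated genes, such as the proliferation list (estimated correlation 0.944). Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.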

Results

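The transcripts of sorted mouse thymocytes were measured on 9 arrays, 1 per group: DP, CD4SP and CD8SP cells of control and Brd1 CKO mice, CD8SP cells of both genotypes from OT-I mice, and CD4SP cells without surface TCRβ of the CKO alone. Between 21667 probes (CD8SP control) and 25489 probes (DP control) were well above background per array, and the 75th percentile of the signal lay between 87.4 (CD4SP control) and 140 intensity units (CD4SP CKO). Levels are log2 signals relative to that percentile, and differences are log2 values, CKO minus control unless stated otherwise. On this scale the median gene detected on both arrays differed by 0.17 in the DP pair, -0.04 in the CD4SP pair, -0.15 in the CD8SP pair and -0.08 in the OT-I pair. Within a pair there was no replicate to check a difference against.

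Brd1 encodes a bromodomain subunit of histone acetyltransferase complexes. Its 1 named probe was well above background on all 9 arrays and was not lower on the arrays labelled CKO. The Brd1 level was -0.79 in the DP control and -0.33 in the DP CKO array, -1.09 and -0.99 in the CD4SP pair, -1.37 and -0.73 in the CD8SP pair, -1.34 and -0.73 in the OT-I pair, and -0.58 in TCRβ-negative CKO cells. The genotype estimate for Brd1 was 0.45 (SE 0.19, adjusted p = 0.475). The position of this probe relative to the deleted part of the gene is not known here, so the probe does not check the deletion. The co-receptor transcripts followed the sorting gates. Cd4 lay between 6.19 and 6.54 on the DP and CD4SP arrays and between 3.14 and 3.50 on the CD8SP and OT-I arrays. Cd8a was 5.46 in DP control and 4.71 in DP CKO cells, -1.22 and -2.11 in the CD4SP pair, 4.60 and 4.70 in the CD8SP pair, and 4.86 and 4.60 in the OT-I pair. Cd8b1 ranged from 6.65 in DP control to 0.54 in CD4SP CKO cells. TCRβ-negative CD4SP cells had Cd4 at 6.19, Cd8a at -0.32 and Cd8b1 at 3.24.

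**Figure D1:**
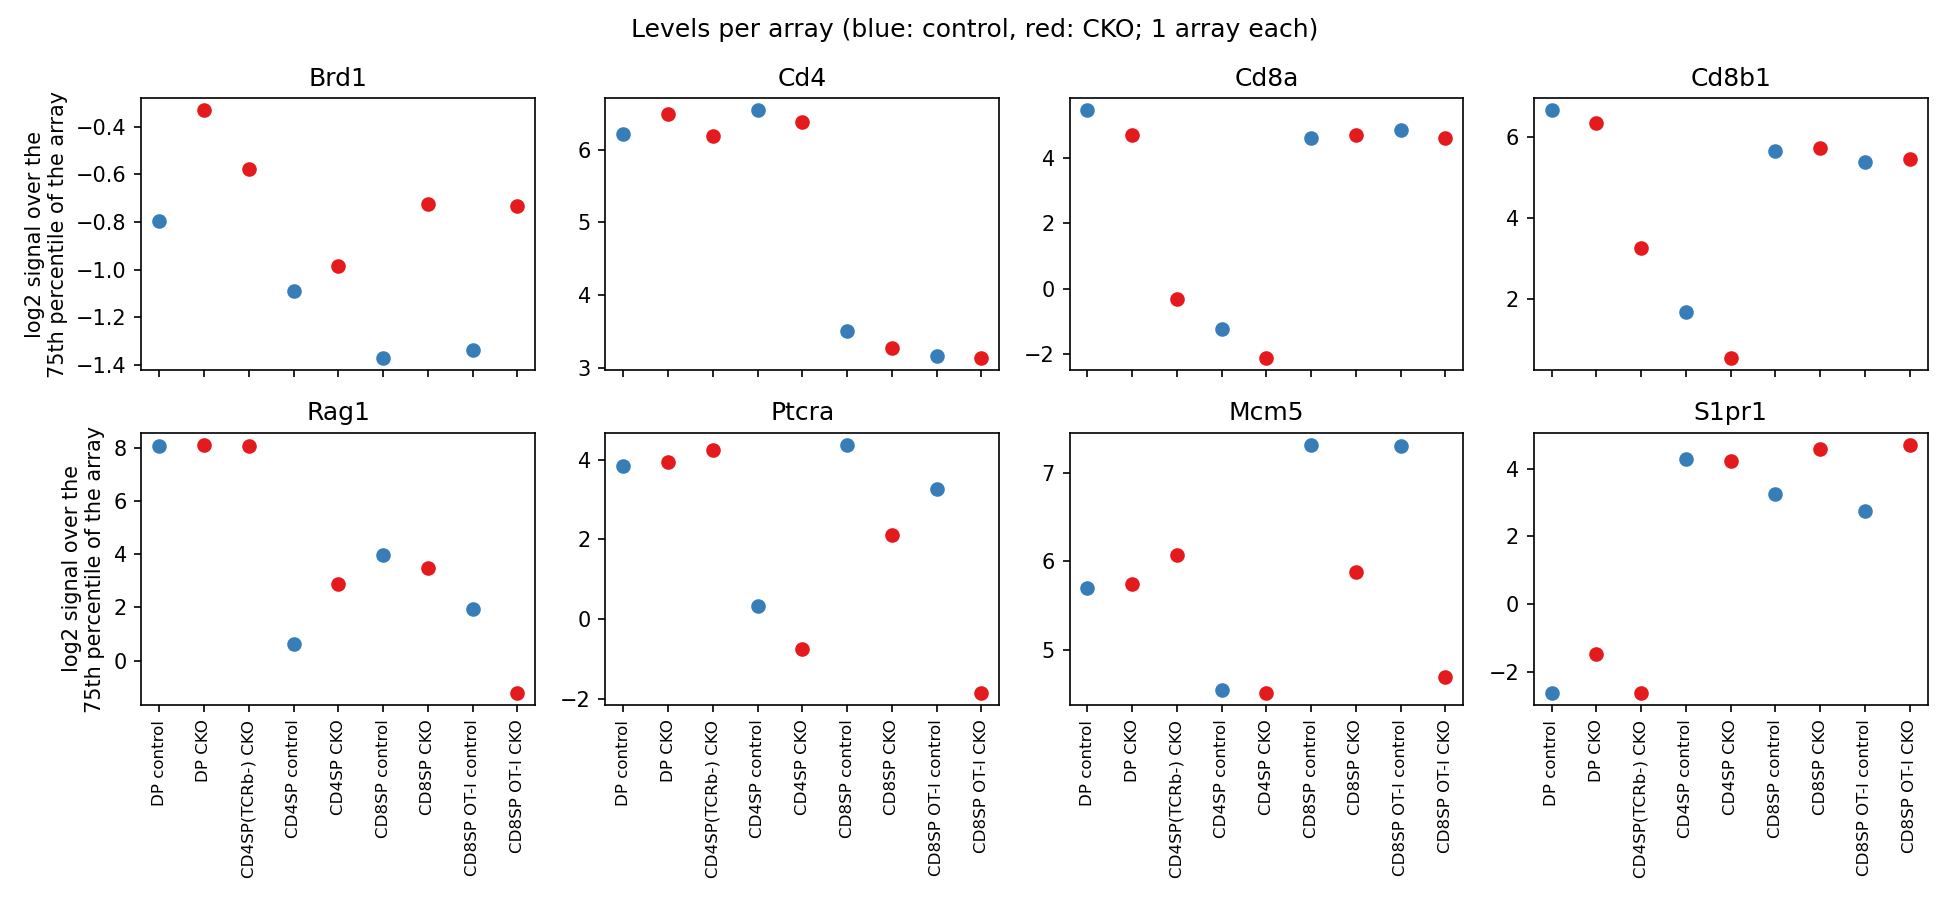
Log2 signal relative to the 75th percentile of the array (vertical axis) for 8 genes on each of the 9 arrays (horizontal axis), blue for control and red for CKO, 1 point per array. Brd1 is not lower on the CKO arrays, Cd4 and Cd8a follow the gates, and Ptcra and Mcm5 are lower in CD8SP CKO and OT-I CKO cells than in their controls.

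The first comparison asked which transcripts differ with Brd1 genotype across the 4 populations measured in both. Of 20282 genes tested with limma, 8 rose and 49 fell in the CKO, each by more than 2-fold, and 46 of these have gene symbols. The 5 named genes that rose were Lalba, the milk protein alpha-lactalbumin (4.32), Rundc3a (2.74), Igsf23 (2.49), Tlr1, a Toll-like receptor (2.23; well above background on 3 of 4 arrays of each genotype), and Fbxo27, an F-box protein (1.68; 3 of 4 control arrays). The largest fitted falls were in Sqor, the mitochondrial sulfide oxidase (-5.10; well above background on 2 of 4 CKO arrays), Igsf3 (-4.54, at least -3.35 against the detection floor), Nhsl1 (-4.40; 1 of 4 CKO arrays), Lysmd2 (-4.06; 1 of 4) and Qpct, glutaminyl cyclase (-3.84; 3 of 4). Raver2 (-3.63; 2 of 4), Tmcc3 (-3.52; 3 of 4), the cytoskeletal GTPase Septin8 (-3.48; 2 of 4), the heparan sulfate proteoglycan Gpc1 (-3.43) and Bex1 (-3.43, at least -2.67) fell as well. The standard errors of these 15 genes were 0.19 to 0.50 and their adjusted p 0.0194 to 0.0488 (4 CKO and 4 control arrays). These are 1 array per population, and those at 8 weeks are not known to come from separate mice. All 57 calls, which were made on the same arrays, went the same way, by at least 2-fold, on the arrays of slide 1 alone (median size 2.62), on the OT-I pair of slide 2 alone (3.05) and with slide as a block (2.80, against 2.88 without). Fitted with slide as a block (2 residual degrees of freedom), limma called 0 genes (1197 at an unadjusted p below 0.05). Only the CD8SP pair crosses slides, so the slide term takes up that pair. For genotype this fit is therefore the same as the one without the CD8SP pair and is no separate check. Limma called 0 without the DP or the CD4SP pair as well. Without the OT-I pair it called 24, of which 16 were among the 57. In each of these fits all 57 kept their direction and an unadjusted p below 0.05. On slide 1 alone (6 arrays, 1 residual degree of freedom) limma called 132. The split of calls depended on the scaling: 1 rose and 31 fell with the 75th percentile of probes detected on all arrays, and 25 rose and 27 fell with normexp.

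**Figure D2:**
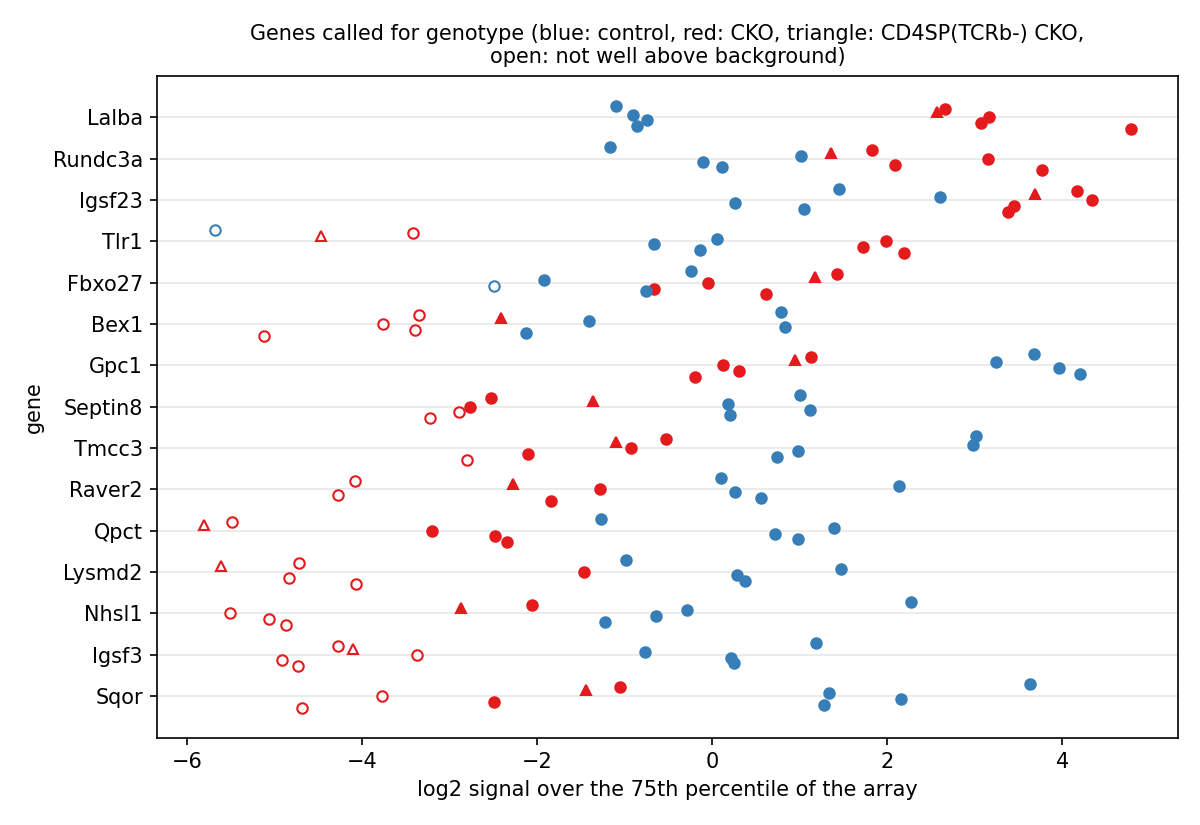
Log2 signal relative to the 75th percentile of the array (horizontal axis) of the 15 named genes called for genotype (rows), blue for control and red for CKO arrays. A triangle marks TCRβ-negative CKO cells, and open symbols mark arrays where no probe of the gene was well above background. Lalba is higher by 4.32 over the 4 CKO arrays, and Sqor is lower (fitted -5.10, with 2 of 4 CKO arrays well above background).

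Among the gene lists, proliferation genes had a fitted median of -1.03 over the 4 populations (0 of 24 members positive), against -3.12 in the OT-I pair, -1.13 in the CD8SP pair, -0.17 in the DP pair and 0.18 in the CD4SP pair alone. Their largest fitted differences were in Cdc6 (-1.81), Ccnb1 (-1.49), Ccna2 (-1.42) and Aurka (-1.27). The list test gave adjusted p = 6.9e-07 at the preset correlation and adjusted p = 0.588 with an estimated correlation. Mature thymocyte and egress genes were higher (median 0.66, 23 of 26 members positive, 0.08 in the CD4SP pair alone; adjusted p = 6.9e-07 preset, adjusted p = 0.588 with an estimated correlation). Their members included Il7r, the interleukin-7 receptor (1.93), Gimap3 (1.60), Ms4a4b (1.55) and the galectin Lgals1 (-1.86). No member of any list passed over all genes; adjusted over the list alone, 7 mature and egress genes rose and 2 fell. Cytotoxic and memory-like CD8 genes had a median of 0.50 (15 of 19 positive; 4 rose adjusted over the list alone), with Ifng at 2.23 (well above background on 2 of 4 control arrays), Ccl5 at 1.99 and Ccl4 at 1.98. Medians were 0.37 for TCR complex genes (2 rose over the list alone; Fyn 1.06, Ptpn22 0.99), 0.36 for TCR signal genes (2 rose and 1 fell; Cd69 1.31, Itm2a -0.85), 0.36 for immediate early genes (5 rose; Fosb 1.26, Hspa1a -1.14, Junb 0.95, Jun -0.92) and 0.45 for interferon-stimulated genes (0 called; Irf7 1.24). CD8 lineage genes (0.61; Eomes 1.43, with 3 of 4 CKO and 2 of 4 control arrays well above background), cytokine and receptor genes (0.44, -0.17 without a detection filter; Il6ra 1.61) and B cell markers (0.51) also passed at the preset correlation. All these lists had adjusted p = 0.588 with an estimated correlation.

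Lists that passed at neither correlation were DP stage genes (median -0.50; adjusted p = 0.176 preset; Ptcra, the pre-TCR alpha chain, -2.08, Tdrd5 1.07), CD4 lineage genes (-0.20), T lineage transcription factors (0.02), Brd1 and partners (0.05), regulatory T cell genes (0.36), sex-linked genes (0.29, -0.01 with normexp), and markers of granulocytes (-0.99), gamma delta T cells (-0.37), erythroid cells (0.42), myeloid cells (-0.20) and stroma (-0.38). The DN stage and Notch list had a median of -0.04 (0.01 with the 75th percentile of detected probes) and a mean of 0.12, and the p53 and apoptosis list a median of 0.02 and a mean of -0.15, so that median and test differed in sign; neither passed, although 1 DN stage gene rose and 1 p53 gene fell adjusted over the list alone. Too few members were tested in the co-receptor list (median -0.32) and the NK and NKT list (-0.25). The proliferation list had a median of -0.01 on slide 1, -3.17 on slide 2 and -0.96 with slide as a block, and the DP stage list 0.56, -2.87 and -0.38. The mature and egress list had 0.38, 1.19 and 0.52.

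DP cells are the immediate precursors of single-positive thymocytes. In them the highest list medians, CKO minus control, were those of regulatory T cell, DN stage and Notch target, erythroid and mature thymocyte genes. Granulocyte genes had the lowest median. Proliferation genes had a median of -0.17 (5 of 24 positive, percentile 0), against 0.17 for all genes. With normexp 63 of 96 named gene differences followed in the 4 pairs came out smaller by over 1.5-fold, so sizes below depend on the background correction. In the DP pair 782 genes were more than 2-fold higher and 1065 lower in the CKO array among 20081 compared. The highest differences were in Xdh, xanthine dehydrogenase (5.67), Slc23a3 (at least 5.06), Lalba (3.75), the adhesion molecule Epcam (3.11), Rundc3a (2.99), the transcription factor Lyl1 (2.83), the chemokine Ccl4 (2.81), Igsf23 (2.71), Stra8 (2.70) and Ly6d (2.67). The lowest were in the granulocyte proteins S100a9 (-5.59) and S100a8 (at least -4.59), Lrig1 (at least -4.76), the pseudokinase Trib2 (-4.75), Sqor (-4.68), Igsf3 (at least -4.45), Nhsl1 (-4.32), Bex1 (at least -4.06), Tmcc3 (-3.54) and Septin8 (-3.52). Granulocyte markers were lower together (median -3.40, 4 of 5 more than 2-fold lower; percentile 0), also Camp (-3.40) and Mpo (-2.14). Erythroid markers had a median of 0.76 (Hbb-b2 1.84, Car2 at least -2.88). DN stage and Notch target genes had a median of 0.77 (percentile 100), with 6 of 12 more than 2-fold higher, among them the Notch target Dtx1 (2.47), Myc (1.42) and Il2ra (1.29). Regulatory T cell genes had a median of 1.04 (5 of 10 more than 2-fold higher; Ctla4 at least 1.82, Lrrc32 1.44, Ikzf2 -1.56). Mature thymocyte and egress genes had a median of 0.53 (Il7r 2.01, Ms4a4b 1.91, Gimap3 1.66, Lgals1 -1.25) and cytotoxic genes one of 0.46 (Gzma 2.24, Ccl5 2.07). The DP stage list had a median of 0.15 against 0.17 for all genes, -0.07 with the 75th percentile of detected probes and -0.06 with quantile normalization. With the 75th percentile of detected probes 479 genes were higher and 1610 lower.

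In CD4SP cells, the CKO array had more transcript of 8 of 16 DP stage genes than the control array. It had less of CD4 lineage genes and of NK and NKT cell, erythroid, granulocyte and myeloid markers. In this pair 684 genes were more than 2-fold higher and 1039 lower in the CKO array among 19791 compared. The highest were Lalba (4.07), Xdh (at least 3.76), Best3 (at least 3.74), the smooth muscle actin Actg2 (3.42), Mr1, which presents antigen to MAIT cells (3.29), Speer4d (2.83), the decarboxylase Ddc (2.76), granzyme A Gzma (2.56), Rag1 (2.26) and the immunoglobulin joining chain Jchain (2.19). The lowest were the kallikreins Klk1b5 (at least -6.99), Klk1 (at least -5.85) and Klk1b24 (at least -5.34), Cox6a2 (at least -5.03), the NK receptors Klra8 (at least -4.98) and Klrb1c (at least -4.85), Adh1 (at least -4.86), Gprasp2 (-4.81), Sqor (at least -4.78) and Tff1 (at least -4.74). DP stage genes were higher (median 0.96, percentile 100), 8 of 16 by more than 2-fold, Rag1, Endou (2.11) and Arpp21 (1.70) among them, with Ptcra at -1.08. CD4 lineage genes had a median of -0.70 (percentile 0), with St8sia6 (-1.96), Ccr4 (-0.84), Tnfrsf4, the costimulatory receptor OX40 (-0.75), and the CD4 lineage factor Zbtb7b (-0.73). Markers of other cells were lower in the same array: NK and NKT cells (median -1.78, 4 of 6 more than 2-fold lower), erythroid cells (-0.98; Hbb-b2 -1.60), granulocytes (-0.75; S100a8 -2.94) and myeloid cells (-0.59; Tyrobp -2.35, Mpeg1 -2.23). B cell markers were not lower (median 0.23, 4 of 6 positive). Proliferation genes had a median of 0.18, with 12 of 23 positive.

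In CD8SP cells, the CKO array had less transcript of cell cycle and DP stage genes than the control array and more of mature thymocyte, interferon-stimulated and cytotoxic genes. In this pair 1253 genes were more than 2-fold higher and 1714 lower in the CKO array among 18610 compared. The highest were the chemokine Ccl3 (at least 4.06), Lalba (3.81), interferon gamma Ifng (3.54), Cox6a2 (3.43), granzyme B Gzmb (3.26), Igsf23 (3.19), the kallikreins Klk1b27 (3.04), Klk1b5 (3.02) and Klk1b8 (2.75), and Ccl5 (2.87). The lowest were Ppic (at least -5.07), Sqor (-4.65), Actl9 (at least -4.58), Prelid2 (-4.05), lactate dehydrogenase B Ldhb (-3.67), Gpc1 (-3.66), Drc1 (-3.61), Egfl7 (-2.73), Cdc42ep4 (-2.60) and the histone H2ac1 (-2.56). All 24 proliferation genes were lower (median -1.13, percentile 0), 16 of them by more than 2-fold, with the replication licensing factor Cdc6 (-2.02), cyclins Ccnb1 (-1.74) and Ccna2 (-1.70) and Aurka (-1.56). DP stage genes had a median of -0.75 (percentile 0), with Ptcra at -2.25 and Slc29a1 at -1.29. Mature thymocyte and egress genes had a median of 1.07 (14 of 26 more than 2-fold higher; S100a4 2.74, Lgals1 -2.03, S100a6 1.94, Il7r 1.81), and cytotoxic genes one of 0.64 (Fasl 3.12). Interferon-stimulated genes had a median of 0.79 with 17 of 18 positive (Ifit1 1.34, Irf7 1.32), CD8 lineage genes one of 0.68 with all 8 positive (Eomes 1.80, Cst7 1.05), and TCR signal genes one of 0.57 (Cd69 2.12). Markers of B cells (median 0.50; Blnk 2.21) and of myeloid cells (0.43; Tyrobp 1.41, Itgax 1.20, C1qb at least -1.13) were also higher in this array. The arrays of this pair lay on different slides, so slide and genotype cannot be told apart within it. With the 75th percentile of probes detected on all arrays, 1672 genes were higher and 1269 lower.

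In CD8SP cells from OT-I mice, whose T cells carry a transgenic receptor restricted by MHC class I, cell cycle and DP stage transcripts were again lower in the CKO array and mature thymocyte and CD8 lineage transcripts higher. In this pair 1573 genes were more than 2-fold higher and 2564 lower in the CKO array among 18621 compared. All 24 proliferation genes were more than 2-fold lower (median -3.12, percentile 0), among them the mitotic kinase Plk1 (-3.74), the ribonucleotide reductase Rrm2 (-3.69), Ccna2 (-3.64) and Ccnb1 (-3.63). DP stage genes were also lower (median -2.87, 13 of 16 more than 2-fold), with Ptcra (-5.11), Aqp11 (-3.78), Endou (-3.62) and Rag2 (at least -3.36); Tdrd5 was higher (1.33). Mature thymocyte and egress genes had a median of 1.19 (15 of 26 more than 2-fold higher; Il7r 3.67, S100a4 2.48, Lgals1 -2.34, Gimap3 2.33), CD8 lineage genes one of 1.23 (Ctsw 2.14, Nkg7 2.00, Eomes 1.99), interferon-stimulated genes one of 0.83 (Ifi27l2a 3.27, Oas1a 3.15) and immediate early genes one of 0.82 (Hspa1a 2.79, against -2.32, -3.06 and -1.99 in the DP, CD4SP and CD8SP pairs). Cytotoxic genes had a median of 0.75, with Ifng (at least 2.95) and Il2rb (2.57) higher and Gzma lower (-3.31). Gamma delta T cell markers had a median of -1.46 (Cd163l1 -2.05), and erythroid markers one of 0.83 (Car2 2.41, Hbb-b2 2.16). Outside the lists, the highest were the acyltransferase Gpat2 (at least 7.88), Lalba (5.65), Npdc1 (4.60), Ifi214 (at least 4.29), Unc5a (4.17), the growth factor Pdgfb (4.02), the NADPH oxidase subunit Ncf1 (3.88), the selectin ligand fucosyltransferase Fut7 (3.70) and Rundc3a (3.66). The lowest were Drc1 (at least -6.04), Slc35f2 (at least -5.76), Spsb4 (at least -5.37), Ybx3 (-4.96), Eras (at least -4.93), Armcx2 (-4.92), Pdlim4 (-4.79), the meiotic factor Mnd1 (at least -4.71) and Nxf3 (at least -4.70). Both arrays lay on slide 2. The split was 2691 higher and 1737 lower with the 75th percentile of probes detected on all arrays, and 631 and 1647 with normexp.

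**Figure D3:**
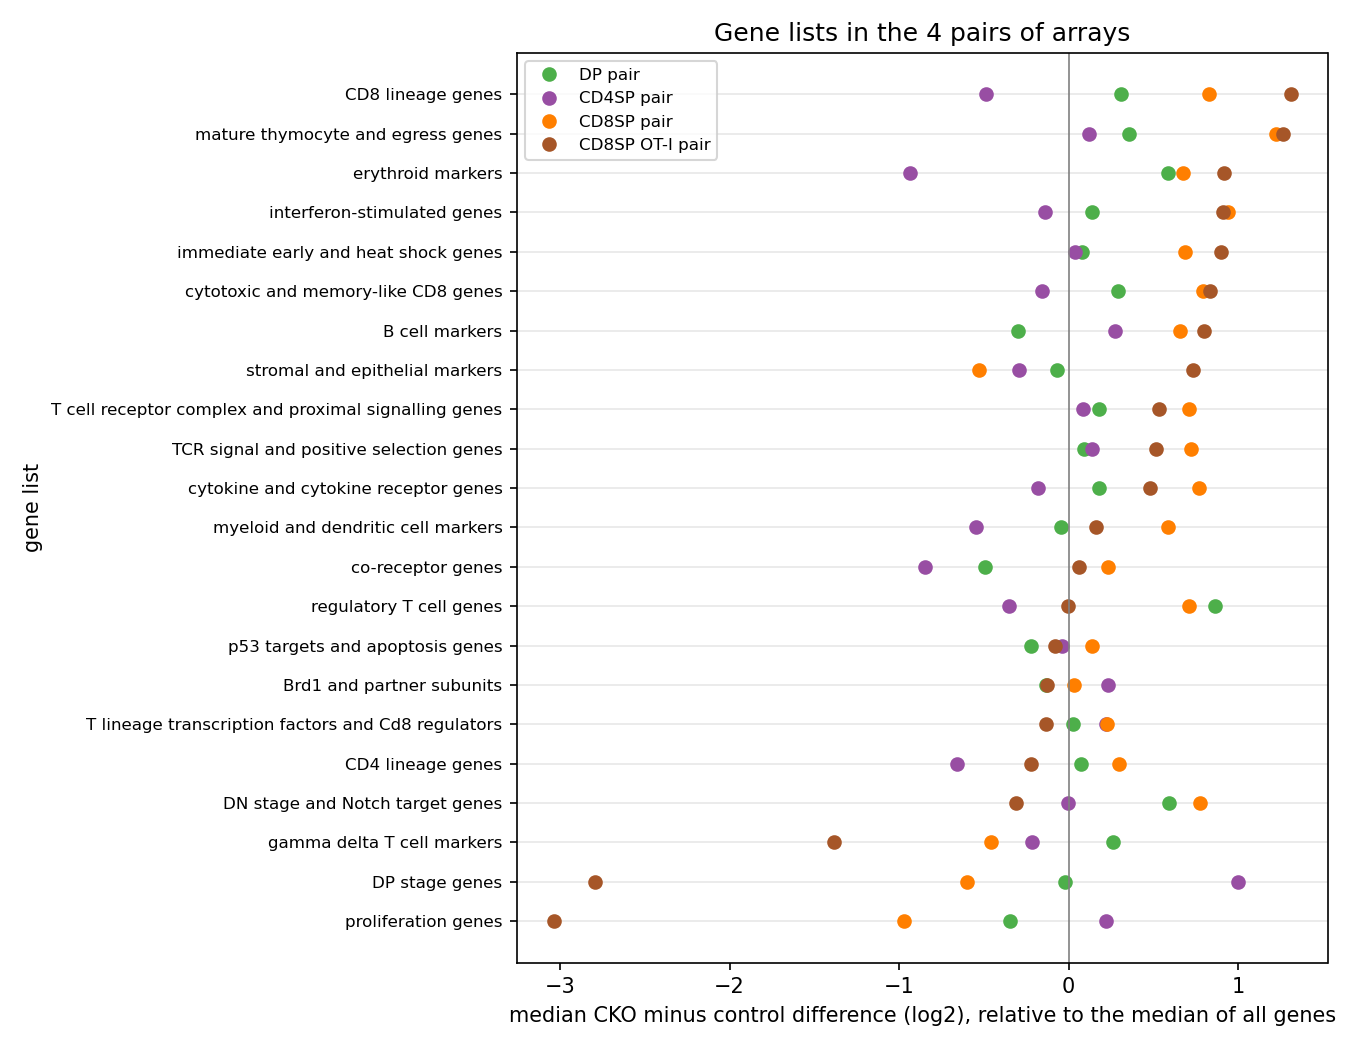
Median difference between CKO and control (log2, relative to the median of all genes in the pair, horizontal axis) of the gene lists with at least 3 members in every pair (rows), 1 point per pair of arrays. Proliferation genes lie at -3.04 in the OT-I pair and -0.97 in the CD8SP pair; DP stage genes lie at 1.00 in the CD4SP pair and -2.79 in the OT-I pair.

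Across 15102 genes, which are not independent replicates, the genotype differences of the CD8SP and OT-I pairs correlated with Pearson's r = 0.70 and Spearman's rho = 0.70. The other 5 combinations of pairs, which like this one share no array, gave r of 0.40 (CD4SP and CD8SP), 0.15 (CD4SP and OT-I), 0.14 (DP and CD4SP), 0.02 (DP and CD8SP) and -9e-04 (DP and OT-I), with rho between -0.09 and 0.37. Without a detection filter the first r was 0.39.

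The population contrasts asked how single-positive cells differ from their DP precursors in these sorts. CD4SP cells had more transcript of egress, interferon-stimulated and TCR signal genes and less of DP stage genes. As lists these passed at the preset correlation alone (adjusted p = 0.265 for each with an estimated correlation). In CD4SP cells against DP cells (2 arrays each), 439 genes rose and 187 fell. The largest fitted rises were in Penk, proenkephalin (6.81, at least 4.84), Apol9b (6.60), Slfn1 (6.50, at least 5.34), the egress receptor S1pr1 (6.31), the dNTP hydrolase Samhd1 (6.27), Igfbp4 (6.21, at least 4.81), the prostacyclin receptor Ptgir (6.19), Nt5e, which encodes CD73 (5.97, at least 4.37), Vipr1 (5.92) and Tnfrsf4 (5.86). The largest falls were in Cd8a (-6.75), Tctex1d1 (-6.51), the recombinase Rag1 (-6.33), Insl5 (-5.79), the sodium channel subunit Scn2b (-5.51, at least -5.04), Cd8b1 (-5.39), Smoc1 (-5.21, at least -4.18), Fbln2 (-5.05), Cbfa2t3 (-4.97) and Morc1 (-4.81, at least -4.22). Their standard errors were 0.34 to 1.20 and adjusted p 0.00982 to 0.0498. Only 1 of 2 DP arrays was well above background for Apol9b and Ptgir and for Cxcr3 and Ifit3 below, and only 1 of 2 CD4SP arrays for Tctex1d1, Insl5, Fbln2 and Cbfa2t3. Of 26 mature thymocyte and egress genes, 15 rose over all genes and 20 rose and 1 fell adjusted over the list alone (median 2.94; Il7r 5.59, Ccr7 5.24, Gimap4 5.20). Interferon-stimulated genes (9 of 18 rose, 16 over the list alone; Ifit1 5.77, at least 4.13, and Ifit3 5.48), TCR signal genes (6 of 17, 14 over the list alone; Rgs1 4.37, Cd53 3.95), cytotoxic genes (6 of 19, 14 over the list alone; Cxcr3 5.13), regulatory T cell genes (5 of 11, 7 over the list alone; Gpr83 4.25, at least 1.95) and CD4 lineage genes (3 of 8, 5 over the list alone; Icos 4.23) rose too. Myeloid markers rose in the same arrays, 2 of 17 over all genes and 10 over the list alone (median 1.72; Cd74 2.13, Lyz1 2.00). DP stage genes fell (median -4.09; 5 of 16, 14 over the list alone). All of these lists passed at the preset correlation, with adjusted p = 0.265 for each with an estimated correlation. Proliferation genes had a median of -2.40 with no member called (adjusted p = 1.0e-09 preset, adjusted p = 0.456 with an estimated correlation). Cytokine and receptor genes (median 1.35; 3 of 11 rose, 6 rose and 1 fell over the list alone) and immediate early genes (median 0.26) were higher at the preset correlation, each with adjusted p = 0.456 with an estimated correlation. The 4 arrays lay on slide 1. With slide as a block 210 rose and 75 fell, and limma on slide 1 alone, with 1 residual degree of freedom, called 2000. Without the CD8SP pair, which for this contrast is the same fit as slide as a block, 210 rose and 75 fell. Without the OT-I pair 519 fell.

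In CD8SP cells against DP cells, cytotoxic, egress, interferon-stimulated and CD8 lineage genes were higher and DP stage genes lower. As lists these passed at the preset correlation alone (adjusted p = 0.665 for each with an estimated correlation). Of all genes, 491 genes rose and 211 fell. Among the largest fitted rises were Adgrg5 (7.71), Dapl1 (6.84), Rab7b (6.78, at least 5.41), annexin A1 Anxa1 (6.77, at least 5.56), Slamf8 (6.70, at least 4.73), Ggt1 (6.55, at least 4.41), Ifi211 (6.54), Trnp1 (6.53, at least 4.75) and the aminopeptidase Anpep (6.46, at least 4.65). The largest falls were in the sodium channel subunits Scn4b (-5.69) and Scn2b (-3.75), Smoc1 (-5.41, at least -3.97), Xrra1 (-5.33, at least -3.90), Insl5 (-4.87), Plxnd1 (-3.97), Tmprss4 (-3.58), Wdr78 (-3.36), Il17re (-3.29) and Slc37a2 (-3.25). Their standard errors were 0.30 to 0.90 and adjusted p 0.00558 to 0.0374. For Adgrg5, Dapl1 and Ifi211, and for Xcl1 below, 1 of 2 DP arrays was well above background, and for Scn4b and Insl5 1 of 2 CD8SP arrays. Of 19 cytotoxic genes 10 rose, 18 over the list alone (median 3.48; Xcl1 6.14, Ccl5 5.37), and 13 of 26 mature and egress genes rose, 19 over the list alone (S1pr1 5.97, Ms4a4b 4.87). Of 18 interferon-stimulated genes 9 rose, 14 over the list alone. Of 8 CD8 lineage genes 5 rose and 1 fell, with the same counts over the list alone (Cst7 5.81, Ctsw 4.70, Eomes 4.67, at least 3.11, and Nkg7 4.04). DP stage genes fell (4 of 16, 5 over the list alone; Ets2 -2.74, Tdrd5 -2.50), as did Cd4 (-2.96). Among myeloid and dendritic markers 7 of 17 rose and 2 fell (9 and 4 over the list alone): the MHC class II genes H2-Eb1 (5.14), H2-Ab1 (5.05) and H2-Aa (5.01) and Mpeg1 (4.92) rose, and 2 fell that are outside the naming rule and were chosen after their values were seen, the complement genes C1qc (-4.18, at least -2.43) and C1qa (-3.18, at least -1.43). T lineage transcription factors (median -0.72) and TCR complex genes (-0.39) were lower and regulatory T cell genes (0.84) higher at the preset correlation. Among the factors Id2 (2.87) and Runx3 (2.70) rose and Satb1 (-1.78) and Bcl11b (-1.74) fell. For each of these lists the adjusted p with an estimated correlation was 0.665, except 0.693 for the myeloid list. Proliferation genes were not called (median 0.16). With slide as a block, limma called 0 genes (2704 at an unadjusted p below 0.05). On slide 1 alone, which holds 1 CD8SP array and leaves 1 residual degree of freedom, it called 557. Without the CD4SP pair 95 genes fell.

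TCRβ-negative CD4SP cells, from the CKO alone, were compared with DP and with CD4SP cells. They were measured on 1 array, so both contrasts and their p-values assume that it varies like the others, by the spread of the genotype difference between the other populations. Relative to DP cells they had less Cd8 transcript and, as lists at the preset correlation alone, less of TCR signal genes (adjusted p = 0.444 with an estimated correlation) and more of proliferation genes (adjusted p = 0.715 with an estimated correlation). Against DP cells limma called 0 genes (103 higher and 230 lower at an unadjusted p below 0.05), and limma on slide 1 alone also called 0 (497 at an unadjusted p below 0.05); without a detection filter 17 rose and 1 fell. The co-receptors Cd8a (-5.18, SE 0.43, adjusted p = 0.434) and Cd8b1 (-3.09) were lower and Cd4 differed by -0.15; adjusted over the list alone, both Cd8 genes fell. TCR signal genes were lower (median -0.82, 1 of 17 positive; Cd53 -1.69, Cd69 -1.52; adjusted p = 1.2e-11 preset, adjusted p = 0.444 with an estimated correlation), and proliferation genes higher (median 1.08, 24 of 24 positive; Cdc6 1.46, Bub1 1.37; adjusted p = 1.0e-06 preset, adjusted p = 0.715 with an estimated correlation). The fit subtracted the genotype effect of the other populations, which was -1.03 for proliferation genes. Measured directly against the DP CKO array, a difference chosen after seeing the data, their median was 0.59 (24 of 24 positive) and that of TCR signal genes -0.80. Myeloid markers (-0.65; adjusted p = 0.444 with an estimated correlation) and mature and egress genes (-0.44; Gimap4 -2.56; adjusted p = 0.581 with an estimated correlation) were lower at the preset correlation. So were CD8 lineage (-0.93) and immediate early genes (-0.69), both with adjusted p = 0.444 with an estimated correlation. Cytotoxic genes (-0.65) and B cell markers (-0.74), with adjusted p = 0.527 with an estimated correlation, and TCR complex genes (-0.22), with adjusted p = 0.715 with an estimated correlation, were lower at the preset correlation too. DP stage genes did not pass (Rag1 0.15; adjusted p = 0.840 preset), and their median of 0.25 and mean of 0.19 differed in sign from the test.

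Against CD4SP cells, the TCRβ-negative CKO cells had less transcript of egress, TCR signal and interferon-stimulated genes and more of DP stage and proliferation genes. As lists these passed at the preset correlation alone (adjusted p = 0.244, with an estimated correlation, for the lower lists, 0.269 for DP stage and 0.368 for proliferation genes). With the same assumption about the single array, 47 of all genes rose and 237 fell. The largest fitted falls were in Samhd1 (-8.88), Ptgir (-8.42, at least -6.23), the interferon-stimulated Oasl2 (-7.93, at least -5.88), Gimap4 (-7.76), Vipr1 (-7.66), the TGF-beta inhibitor Smad7 (-7.61, at least -5.03), Slfn1 (-7.50, at least -5.43), Gpr18 (-7.45, at least -5.60), S1pr1 (-7.43) and Bcl3 (-7.33). Among the largest fitted rises were Scn2b (5.56, at least 4.75), Dpf1 (4.77, at least 4.04), Tmprss4 (4.31; well above background on 1 of 2 CD4SP arrays), Pomgnt2 (4.31), Tdrd5 (4.28), Plxdc1 (4.23), Sytl3 (4.21), Papss2 (3.72) and Fbxl12 (3.38). Their standard errors were 0.35 to 0.93 and adjusted p 0.0269 to 0.0481. Mature and egress genes fell (11 of 26; 20 fell and 2 rose over the list alone; Ccr7 -7.30), as did TCR signal genes (6 of 17, 14 over the list alone; Cd53 -5.64), interferon-stimulated genes (4 of 18, 16 over the list alone), cytotoxic genes (5 of 19, 12 over the list alone), CD4 lineage genes (3 of 8, 3 over the list alone; Tnfrsf4 -6.76) and myeloid markers (4 of 17, 11 over the list alone; Cd74 -3.56); regulatory T cell genes fell too (4 of 11; 7 fell and 1 rose over the list alone). The adjusted p with an estimated correlation was 0.244 for each. DP stage genes were higher (median 4.41; Rag1 6.49, Rag2 5.81), 1 of 16 rising over all genes and 13 over the list alone (adjusted p = 0.269 with an estimated correlation). All 24 proliferation genes were higher (median 3.54), 0 called by limma over all genes and 21 over the list alone (adjusted p = 0.368 with an estimated correlation). Measured directly against the CD4SP CKO array, also chosen after seeing the data, the medians were 3.74 for DP stage, 2.89 for proliferation and -3.20 for mature and egress genes. Immediate early (median -1.04) and cytokine genes (-1.63) were lower at the preset correlation, with adjusted p = 0.269 and adjusted p = 0.368 with an estimated correlation. Limma called 0 genes with slide as a block (2681 at an unadjusted p below 0.05), with quantile normalization or without the DP or the CD8SP pair, and 1373 on slide 1 alone with 1 residual degree of freedom. Without the OT-I pair 217 rose and 365 fell, and 184 rose and 395 fell with normexp.

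In OT-I against polyclonal CD8SP cells, 8 genes rose and 40 fell, and 14 of these have symbols. Xist, the X inactivation transcript, rose (6.20, at least 4.83), and the Y-linked Eif2s3y (-6.48, at least -4.30) and Ddx3y (-5.51, at least -3.54) fell. Xist was well above background on the OT-I arrays of both genotypes alone, and Ddx3y on the 7 other arrays alone, so these populations also differed in the sex of the mice, besides age (14 against 8 weeks) and slide. Gdpd3 fell (-7.78, at least -5.96), as did the stress-response factor Atf3 (-3.43, at least -1.50). Interferon-stimulated genes (median -1.06; Ifi44 -2.69, at least -0.55), cytotoxic genes (-0.95; Xcl1 31.9-fold lower), DP stage genes (-1.14; Rag2 -3.40, with 1 of 2 OT-I arrays well above background, Rag1 -3.35) and myeloid markers (-1.01; Fcer1g -2.73) were lower and TCR signal genes higher (0.75; Rgs1 -2.01, Itm2a 1.47, Bcl2a1d -1.42, Cd5 1.29) at the preset correlation. The adjusted p of these lists was 0.426 with an estimated correlation. No member of these 5 lists was called over all genes; adjusted over the list alone, 3 cytotoxic genes, 1 DP stage gene and 5 myeloid markers fell, and 6 TCR signal genes rose and 2 fell. Proliferation genes (-0.72; adjusted p = 0.566 with an estimated correlation) and regulatory T cell genes (-0.71; adjusted p = 0.426 with an estimated correlation) were lower and TCR complex genes (0.34; adjusted p = 0.426 with an estimated correlation) higher at the preset correlation. Other lists passed at the preset correlation as well. Markers of B cells (median -1.10) and granulocytes (-0.77) and DN stage and Notch genes (-0.28, 0.0064 with detection on all arrays compared) were lower. Gamma delta T cell markers (0.83, -0.094 without a detection filter; 1 of 5 rose over all genes and 2 over the list alone), cytokine genes (0.42) and T lineage factors (0.27) were higher. Each of these had adjusted p = 0.426 with an estimated correlation. Mature and egress genes (-0.17; adjusted p = 0.566 with an estimated correlation) and sex-linked genes (-3.08; 1 rose and 2 fell over all genes, 1 and 3 over the list alone; adjusted p = 0.388 with an estimated correlation) were lower. With slide as a block 2 genes rose and 15 fell, without the DP pair 3 and 24, and without the CD4SP pair 1 and 19.

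On the axis from the DP control (0) to the CD4SP control array (1), over 1907 genes, the median position was 0.13 for DP CKO, 0.82 for CD4SP CKO and 0.02 for TCRβ-negative CKO cells. CD8SP cells lay at 0.55 (control) and 0.68 (CKO), and OT-I cells at 0.46 and 0.80. On the axis to the CD8SP control, over 1848 genes, CD8SP CKO cells lay at 0.76, OT-I control cells at 0.71, OT-I CKO cells at 0.55, CD4SP cells at 0.57 (control) and 0.35 (CKO), DP CKO cells at 0.27 and TCRβ-negative cells at 0.24. With normexp 8 of these 14 positions moved by over 0.1: to 0.93 for CD4SP CKO and 0.92 for OT-I CKO cells on the first axis, and on the second to 1.05 for CD8SP CKO, 0.79 for OT-I CKO, 0.81 and 0.62 for CD4SP control and CKO, 0.16 for DP CKO and 0.13 for TCRβ-negative cells. The array of TCRβ-negative cells correlated most with the DP CKO array across 15071 genes (r = 0.993), against 0.985 with DP control and 0.952 with CD4SP CKO.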

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

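The 3 tests of the genotype calls by other splits of the arrays, by the held-out pair and by share of calls on the chromosome of Brd1 were planned before their results were seen; the limit to splits that part every pair and all other tests in this part were chosen after.

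Of 25 gene lists and the 69 genes named among the largest differences of a pair, 3 lists (by a median of at least 1.5-fold each way) and 6 genes (by at least 2-fold each way, with both arrays of a pair well above background) differed in opposite directions between CKO and control in 2 populations. With differences that are bounds counted as well, 9 more genes did so. In the CD4SP and CD8SP pairs these were Klk1b5 (at least -6.99 and 3.02), Klk1 (at least -5.85 and 2.62), Klk1b24 (at least -5.34 and 2.74), Cox6a2 (at least -5.03 and 3.43), Tff1 (at least -4.74 and at least 3.11), Klk1b8 (at least -4.70 and 2.75) and Klk1b27 (at least -4.33 and 3.04). In the CD4SP and OT-I pairs they were Eras (at least 3.29 and at least -4.93) and Actg2 (3.42 and at least -1.47). Of 174 further genes, the list members with the 4 largest differences in a pair, 21 did so by the same rule and 25 with bounds counted. Among them were Hspa1a (2.79 in the OT-I pair, -3.06 in the CD4SP pair, -2.32 in the DP pair and -1.99 in the CD8SP pair), Endou (2.11 in the CD4SP pair and -3.62 in the OT-I pair) and Car2 (2.41 in the OT-I pair and at least -2.88 in the DP pair). Each value rests on 1 pair of arrays, and the difference between the populations was not tested. DP stage genes had a median of 0.96 in CD4SP cells and -2.87 in OT-I CD8SP cells, and Rag1 differed by 2.26 and -3.14 in the same pairs. Erythroid markers had a median of 0.83 in the OT-I pair and -0.98 in the CD4SP pair, and stromal and epithelial markers 0.66 in the OT-I pair and -0.68 in the CD8SP pair (0.12 where detection on both arrays was required, which removes the opposite directions). Gzma differed by 2.56 in the CD4SP pair and -3.31 in the OT-I pair. Gzmb differed by 3.26 in the CD8SP pair and -2.21 in the CD4SP pair. Pdgfb differed by 4.02 in the OT-I pair and -1.16 in the CD4SP pair. Pdlim4 differed by 1.94 in the DP pair and -4.79 in the OT-I pair, and Stra8 by 2.70 and -4.35 in these pairs.

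The genotype calls across 4 populations were weighed against chance, slide and a strain-derived interval around the targeted gene. Only 8 splits of the arrays part every pair as the real one does, too few for a share under 0.05: of these, 1, the real one, called 57 genes and the highest other called 0; the planned set of 32 splits (1 as large, highest other 1) also holds splits that put both arrays of a population on the same side and are not exchangeable with the real one, and without the DP, CD4SP or CD8SP pair 0 genes were called. Of 24 genes called without the OT-I pair, 17 were comparable in it. Of these, 94.1% differed at least 2-fold the same way within that pair, whose arrays share a slide, against 13.3% of all genes. The DP and CD4SP pairs, on which those calls also rest, lie within slide 1. Slide could therefore hardly have made the calls, and the test says little about it. Acting only on genes within it, an interval carried along with the floxed allele cannot be the source of all calls. Of the named calls, 91.3% lie on other chromosomes (exact 95% interval 79.2% to 97.6%). Such an interval may account for some: 8.70% (4 of 46: Fbln1, Gcat, Lalba and Matn2) lie on the chromosome of Brd1 against 4.02% of all named genes (exact 95% interval 2.42% to 20.8%, two-sided Fisher exact p = 0.113). The chromosome of a call cannot show whether the interval changed genes elsewhere. Loss of Brd1, effects of the interval on genes elsewhere and other strain-derived differences stay open. So do parentage of the mice and differences between single mice, which were not analysed here.

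Lower proliferation and DP stage transcripts in the CD8SP and OT-I CKO arrays were weighed against sorting, slide and scaling. For the proliferation genes, DP cells with the transcript levels of the DP control array cannot explain the control levels alone. The median in the control arrays lay above that of the DP control array by at least 0.77. In CD8SP cells 21 of 24 members lay above it, and 22 of 24 in OT-I cells, and a mixture cannot exceed both of its parts. Cells of the DP gate with more proliferation transcript than that array as a whole are not excluded. This level was compared on the main scale alone. For the OT-I pair slide is excluded, as both arrays share one and the higher of the 2 list medians was -2.87; the CD8SP pair crosses slides and has no such value. Over all scalings and background corrections tried the highest median of either list was -1.70 in the OT-I pair and -0.51 in the CD8SP pair. Scaling is therefore excluded as the source of the direction. The cut-off was chosen after seeing the data and the CD8SP value passed it narrowly, so the size in that pair may depend on scaling. A different share of cycling CD8 immature single-positive cells in the gates may explain it, with Ptcra differing by -2.25 in the CD8SP pair and -5.11 in the OT-I pair, but no array measured such cells alone, the series description names TCRβ among the sorting markers but not the gates it was used for, and a CD8SP gate with it would remove cells without it, and Ptcra lay above the DP control (3.84) in the CD8SP control (4.36) but not in the OT-I control (3.26), so sorting and regulation in mature cells cannot be told apart.

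The CD4SP array without TCRβ lay close to the DP CKO array, with a median DP stage gene at -0.02 relative to it (quartiles -0.10 and 0.03). A DP array under this label, or a gate holding mainly cells with the Cd8 transcript of DP cells, is excluded by Cd8b1 and Cd8a. These lay at -3.09 and -5.03 relative to the DP CKO array, while Cd4 lay at -0.30. The gate itself selects cells low in CD8, so these values cannot exclude DP stage cells that had lowered CD8. A small share of DP cells is not excluded either, as Cd8b1 was 3.24 against 0.54 in the CD4SP CKO array. Whether genotype plays a part cannot be tested without a control array of such cells.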

How the results depend on the processing

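Scaling on the 75th percentile of detected probes and the direct difference of the TCRβ-negative array from a CKO array were chosen after seeing the data; all other alternatives in this part were planned. Of the counts of genes under alternatives, 40 were larger and 67 smaller than the reported count by over 1.5-fold, and the others lay within it. For tested list results, direction was followed only where the list passed in the reported fit, so a change of sign in a list that had not passed was not counted. Among them 1600 kept their side of the threshold, 119 lost the threshold, 31 gained it and 3 that had passed reversed. Of the 119, 66 lost it with the estimated correlation, under which 72 list results stayed the same. All 57 genotype calls kept their direction under the 12 alternatives in which they were followed, with 54 to 57 at an unadjusted p below 0.05. Among these, slide as a block and leaving out the CD8SP pair are the same fit for genotype. Counts below are higher/lower; the cause was not tested except where stated.

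With normexp, genotype gave 25/27, CD4SP against DP 342 lower, CD8SP against DP 1066/491, TCRβ-negative against CD4SP 184/395, OT-I against CD8SP 5 higher, and the DP, CD4SP, CD8SP and OT-I pairs 215/278, 251/260, 566/536 and 631/1647; its offset of 50 shrinks differences of dim probes, and 63 of 96 named gene differences within pairs came out smaller by over 1.5-fold, against 18 moved with no filter and 6 with the mean over probes. With quantile normalization genotype gave 4/25 and TCRβ-negative against CD4SP 0/0. With the detected-probe percentile genotype gave 1/31, CD8SP against DP 292 higher, TCRβ-negative against CD4SP 13/78, OT-I against CD8SP 4/25, the DP pair 479/1610 and the OT-I pair 2691 higher.

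Requiring detection on all arrays compared leaves fewer genes: genotype gave 5/15, TCRβ-negative against DP 1 lower and against CD4SP 97 higher, OT-I against CD8SP 1/6 and the CD4SP pair 444/632. Under it the DN stage and Notch list in OT-I against CD8SP reversed from -0.28 to 0.0064 and the stromal list of the CD8SP pair from -0.68 to 0.12. With no filter, which adds dim probes, genotype gave 13/83, TCRβ-negative against DP 17/1 and against CD4SP 119 higher, the 4 pairs 2143/2351, 1739/2882, 2314/3420 and 2854/3860, and the correlation of the CD8SP and OT-I differences was 0.39; the cytokine list for genotype reversed from 0.44 to -0.17 and the gamma delta list in OT-I against CD8SP from 0.83 to -0.094.

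With slide as a block, which removes a residual degree of freedom and the CD8SP pair's part in the error, genotype gave 0/0, CD4SP against DP 210/75, CD8SP against DP 0/0, TCRβ-negative against CD4SP 0/0 and OT-I against CD8SP 2/15. For contrasts that do not involve CD8SP cells, the fit with slide as a block is the same as the fit without the CD8SP pair. That pair then has no part in the estimate either. Without the population block genotype gave 2/14. With a variance trend genotype gave 21 higher, CD4SP against DP 294 lower, CD8SP against DP 993/363 and TCRβ-negative against CD4SP 123/408.

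Leaving out a pair leaves fewer arrays. Genotype then ranged from 0 to 2 higher and 0 to 22 lower. CD4SP against DP ranged from 210 (without the CD8SP pair) to 657 higher and from 75 to 519 (without the OT-I pair) lower, and CD8SP against DP from 95 (without the CD4SP pair) to 281 lower. TCRβ-negative against CD4SP ranged from 0 to 217 higher and 0 to 365 lower, and OT-I against CD8SP from 1 to 3 higher and 19 to 24 lower.

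Taken directly against the DP or CD4SP CKO array, with no test, 41 list medians of the TCRβ-negative array lay within 1.5-fold of the fitted ones and 5 did not.

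Of 112 axis positions under alternatives 15 moved by over 0.1: 8 of 14 with normexp, 5 with detection on all arrays compared (on the CD4SP axis CD4SP CKO cells to 0.92 and OT-I CKO cells to 0.92, on the CD8SP axis CD4SP control cells to 0.69, CD4SP CKO cells to 0.50 and OT-I CKO cells to 0.72), and 2 with a 2-fold axis (on the CD8SP axis CD8SP CKO cells to 0.65 and OT-I control cells to 0.85).

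At 1.5-fold, a looser threshold, the DP, CD4SP, CD8SP and OT-I pairs gave 2677/2372, 2023/2582, 2794/4244 and 3468/4715; at 4-fold 124/199, 82/274, 163/231 and 258/751. Signal over background limits all of this: 39.01% to 45.9% of probes were well above it, and differences against the other probes are bounds where no array of a group was well above it and otherwise rest partly on signals that were not.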

Other observations

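The genotype calls were followed in the array of TCRβ-negative CKO cells, which does not enter the genotype estimate. This was chosen after the calls were seen. The array correlated most with the DP CKO array (r = 0.993), which does enter the estimate, so it is not an independent check. Of the 57 called genes 50 lay nearer to the CKO mean than to the control mean in it, against 50.6% of all tested genes, and 50 lay beyond every control array on the CKO side, against 23.9%. All 4 CKO arrays lay apart from all 4 control arrays for 39 of the 57 called genes and for 670 of all 20282 tested genes. The calls were made on these same arrays, so this separation adds no support.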
